A study of Mus musculus with 8 samples.

How the data were processed

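RNA from the quadriceps muscle of 8 mice was sequenced as 1 library per mouse. Per the labels' protocols, total RNA was isolated with the RNeasy Mini kit and libraries were made with the Universal Plus mRNA-Seq kit with NuQuant, which selects polyadenylated RNA. The group of each library (4 control, 4 tumor) was taken from its sample label, and each column of the count table was matched to a library by its name. The sex of the mice, the strand setting of the counting and the sequencing batch were not given in the sources used here.

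The authors deposited 1 table of estimated counts for 53819 gene symbols, in which 9% of the values were not whole numbers. Per the submitters' processing notes, the tools were cutadapt 3.4, Trim Galore 0.6.7, STAR 2.7.9a, Salmon 1.10.1 and R 4.2.2, with the mouse genome build GRCm39; the role of each tool and the annotation are not given in the sources used here. An estimated count shares reads that match several genes among them by likelihood, so values of near-identical genes, pseudogenes and overlapping genes are less certain than those of other genes. No coordinates are given, because the reference at hand was of another build. It was used only for transcript length and GC content, matched by gene symbol.

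The deposited estimated counts were rounded to whole numbers. Totals per library ran from 28436254 to 36139478, and 25972 symbols had a count in at least 1 library. Genes were kept by the edgeR function filterByExpr with its default minimum count of 10, which left 14070 genes holding 99.92% of all counts. Normalisation factors were computed by the TMM method. Differences between groups were tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with group as the only term, two-sided, and p-values were adjusted by Benjamini-Hochberg over the 14070 genes, with a threshold of 0.05. The biological coefficient of variation was 30.1%. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Counts per 1000000 (CPM) are scaled by the TMM factors, and means and SDs are over the 4 libraries of a group.

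A total of 46 gene lists (pathways, complexes and markers of cell types that muscle or the tumor could contribute) were fixed before the data were examined, together with the tests and the rule for named genes. Lists with at least 5 tested members (43) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over these lists. For each list the members past the threshold were counted, with p adjusted over all genes and over the list alone. Scores of a list are the mean log2 CPM of its members in a library (prior count 2). Principal components used the 500 most variable genes. Differences in single values per library were tested by an exact permutation test over all splits of the 8 libraries, two-sided, whose smallest p is 0.0286.

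Genes were named by a rule with 4 parts. The first part took the 6 largest rises and the 6 largest falls among changed genes with an average log2 CPM of at least 1, groups without overlap and a symbol that is not a clone or predicted-gene name. The second took up to 4 changed members with the smallest p of each list described, or up to 2 where none changed. The third took a fixed set of genes of muscle wasting and fibre type whatever their result. The last took the squamous epithelial markers with the highest counts. A result that the rule would name is not reported here. A fall is also given as a fold, the inverse of the ratio of tumor to control. For genes at 0 counts, the level that 3 counts would give was used as the upper limit.

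The steps were tested on negative binomial counts simulated for 14070 genes from the means, dispersions and library sizes of the 8 libraries. The count filter then kept 13814 of these. Of 100 genes changed 2-fold, 39% were called, and of 100 changed 4-fold, 77%, with 0 of the wrong sign. Of 127 genes called, 6 (4.72%) were unchanged genes. A list of 30 genes shifted by 0.8 on the log2 scale was called and 0 of 40 unchanged lists were. Genes were drawn independently of each other, so this did not test list calls where members move together. In the real libraries, splits with equal shares of both groups on each side called up to 24 lists. Far fewer genes were changed in the simulation than were called in the data (2781), so a smaller unadjusted p was needed there. The shares recovered therefore do not give the power of the real comparison. Libraries of a group differed by more than sampling noise, so all 8 were kept as separate.

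Alternatives were run for scaling (DESeq2 size factors, upper quartile, and scaling without the 50 most abundant and the mitochondrial genes), for the count filter (none, or at least 1 CPM throughout a group and a mean count of 50), for each library left out in turn, for the replicate number as a block, for other tests (DESeq2 1.42.0, limma-voom with and without quality weights) and for other thresholds. List tests were repeated with an estimated correlation, with fry and on limma-voom values. A fit with the log2 ratio of Myh4 to Myh1, Myh2 and Myh7 as a covariate, and a fit without control library 4 and tumor library 2, were added after the data had been seen.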

Results

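The series measured messenger RNA in the quadriceps muscle of C57BL/6J mice that carried a head and neck squamous cell carcinoma, to characterise the muscle wasting (cachexia) that this tumor causes. Mice were 8 weeks old at the start. In the tumor group, 4 mice received 500000 cells of the carcinoma line B0092 under the skin at the nape of the neck, and 4 control mice received the saline vehicle alone. Muscle was taken on day 36, a time that the series description sets by a weight loss of about 10% from the start. Each of the 8 libraries came from a separate mouse, so the spread within a group covers differences between animals. The libraries held 28436254 to 36139478 counts, and 14070 genes were counted deeply enough to be tested.

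The principal component that carried 36.7% of the variance among the most variable genes placed the 4 controls between -29.8 and -9.0 and tumor libraries 1, 3 and 4 between 21.2 and 31.2, with tumor library 2 at -1.4. The next component (22.3% of the variance) set control library 4 apart at -45.2, and the following one (18.8%) set tumor library 2 apart at 42.1. Both libraries differed from their groups in fibre composition. Myh4, the myosin heavy chain of the fastest fibres (type 2B), made up 64.6% of the adult myosin heavy chain counts in control library 4 and 88.5% to 98.0% in the other controls. It made up 80.3% in tumor library 2 and 95.2% to 98.9% in the other tumor libraries. The log2 ratio of Myh4 to the sum of Myh1, Myh2 and Myh7 was 3.42 ± 2.02 in controls and 4.72 ± 2.02 in tumor mice (SD, n = 4 each, two-sided exact permutation p = 0.4).

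With all 8 libraries, most proteasome and ribosomal protein genes rose in tumor-bearing mice and most nuclear respiratory chain genes fell. Parts of the matrix and vascular lists also fell. For the ribosomal protein and respiratory chain genes, a majority was not reached without some single libraries, as given below. Of the 14070 genes, 2781 (19.8%) changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 1552 of them higher and 1229 lower in tumor mice. At least 2-fold changes were found for 352 higher and 551 lower genes. All 4 tumor values lay on one side of all 4 control values in 3515 genes (25.0%, where chance gives 2.86%), among them 2480 of the changed genes. Other splits of the 8 libraries into 4 and 4 called at most 43 genes. With upper-quartile scaling 43.0% of the called genes were higher (1169 higher and 1547 lower). Leaving out 1 library lowered the count to 1110 without control library 1, 1373 without control library 2 and 1190 without tumor library 3. It left 1004 higher genes without control library 3.

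Among genes with an average log2 CPM of at least 1 and groups without overlap, the largest rises were those of Ggt6 (25.1-fold), Depp1 (13.7-fold), Ddit4 (13-fold), Cebpd (12.2-fold), Ankrd1 (11.4-fold) and Krt80 (11.3-fold). Depp1 is a FOXO target, Ddit4 an inhibitor of the growth kinase complex mTORC1, Cebpd a transcription factor of the acute phase response and Ankrd1 a stress-responsive sarcomere protein. Ddit4 went from 2.49 ± 0.90 to 32.5 ± 25.5 counts per 1000000 (CPM; SD, n = 4), with a log2 fold change of 3.70 ± 0.60 (SE) and an adjusted p of 0.00508 in the edgeR test. Under the same limits the largest falls were those of Nrep (22.3-fold), the lysine methyltransferase gene Mettl21c (18.2-fold), the cardiac actin gene Actc1 (13.3-fold), Foxo6os (12.3-fold), Amd-ps3 (11-fold) and the water channel gene Aqp4 (9.83-fold). Nrep went from 98.2 ± 25.6 to 4.41 ± 3.41 CPM, with a log2 fold change of -4.48 ± 0.48 and an adjusted p of 0.00233 in the edgeR test. Foxo6os overlaps Foxo6 on the opposite strand and Amd-ps3 is a pseudogene copy of Amd1, so reads could be shared between them and their values are uncertain. Krt80 lost its call without control libraries 1, 2, 3 or 4 or tumor libraries 3 or 4 (adjusted p from 0.0559 to 0.091). Ankrd1 lost it without control libraries 1, 2 or 3 or tumor library 3 (adjusted p from 0.0501 to 0.0655). Tumor library 4 carried much of these rises: without it the folds were 3.00 for Krt80, 5.09 for Ankrd1 and 12.4 for Ggt6, and Ggt6 was 40.3-fold higher without control library 3. Ggt6 lay between 0.07 and 0.35 CPM in controls, and limma-voom did not call it (adjusted p = 0.0807). The rise was 8.36-fold for Ddit4 without tumor library 2 and 27.5-fold for Depp1 without control library 4. Without tumor library 1 the falls were 36.1-fold for Nrep, 34.4-fold for Mettl21c and 24.5-fold for Actc1, and that of Actc1 was 8.56-fold without control library 3.

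Proteasome subunit genes rose together, and atrophy-related ubiquitin genes rose in part. Both muscle-specific ubiquitin ligases that mark atrophy were higher in tumor mice. Trim63 (MuRF1) rose 4.5-fold, from 327 ± 83.5 to 1469 ± 922 CPM (SD, n = 4), with a log2 fold change of 2.17 ± 0.43 (SE) and an adjusted p of 0.00981 in the edgeR test. Fbxo32 (atrogin-1) rose 3.41-fold, from 683 ± 283 to 2332 ± 1261 CPM, with a log2 fold change of 1.77 ± 0.45 and an adjusted p of 0.0258, and its groups overlapped. The Fbxo32 call was lost without control library 1 (adjusted p = 0.0799), control library 2 (adjusted p = 0.0755) or tumor library 3 (adjusted p = 0.0709). Of 33 proteasome subunit genes, 28 rose (31 adjusted over the list alone), and the list median was a log2 fold change of 0.80. Psmd2 and Psmd4, subunits of the regulatory particle, rose 2.94-fold (1.56 ± 0.20 on the log2 scale, adjusted p = 0.0031) and 2.91-fold (1.54 ± 0.19, adjusted p = 0.00294). Psmc2, an ATPase of the same particle, rose 2.07-fold. Among 23 atrophy-related ubiquitin genes 6 rose and 2 fell (the same counts adjusted over the list alone), including the polyubiquitin gene Ubb (2.04-fold) and the deubiquitinase gene Usp2 (1.55-fold). Without control library 1 this fell to 2 higher genes, and Ubb was no longer called (adjusted p = 0.0524). Without control library 2 or tumor library 3 it fell to 3, and the 2 lower genes became 1 without tumor library 1 or 2 and 0 without any other library. The ligase gene Fbxo30 did not pass (log2 fold change 0.44 ± 0.23, adjusted p = 0.2), but it passed without control library 4 (adjusted p = 0.036), without that library and tumor library 2 (adjusted p = 0.0416) and by limma-voom with quality weights (adjusted p = 0.0122).

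Parts of the autophagy and of the FOXO or glucocorticoid receptor target lists also rose. Of 31 autophagy and lysosome genes, 14 rose, with a median log2 fold change of 0.50 (18 higher and 1 lower adjusted over the list alone). Gabarap, which conjugates to autophagosome membranes, rose 1.81-fold and the cargo receptor gene Sqstm1 rose 1.97-fold, from 519 ± 91.9 to 1021 ± 169 CPM. The autophagy count was 7 without control library 1, and 8 without control library 2 or tumor library 3. Of 30 FOXO or glucocorticoid target genes, 16 rose and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 1.28, and 10 rose without control library 1. The median was 0.84 without tumor library 2. Eif4ebp1, a repressor of cap-dependent translation, rose 4.96-fold (2.31 ± 0.25 on the log2 scale, adjusted p = 0.00233, edgeR). The clock gene Per1 rose 5.98-fold, the growth arrest gene Gadd45a 3.59-fold and the glutamine synthetase gene Glul 4.13-fold. Cdkn1a, a cell cycle inhibitor, rose 4.29-fold (2.10 ± 0.35 on the log2 scale, adjusted p = 0.00538). Foxo1 itself lay at the threshold (log2 fold change 1.30 ± 0.41, adjusted p = 0.0495), and left-out fits gave it an adjusted p from 0.0667 to 0.118 without control libraries 1, 2, 3 or 4 or tumor libraries 2 or 3 (log2 fold change 0.66 without tumor library 2). Pdk4 had a log2 fold change of 1.13 ± 0.57 (adjusted p = 0.193), which passed without tumor library 4 (adjusted p = 0.0388).

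**Figure D1:**
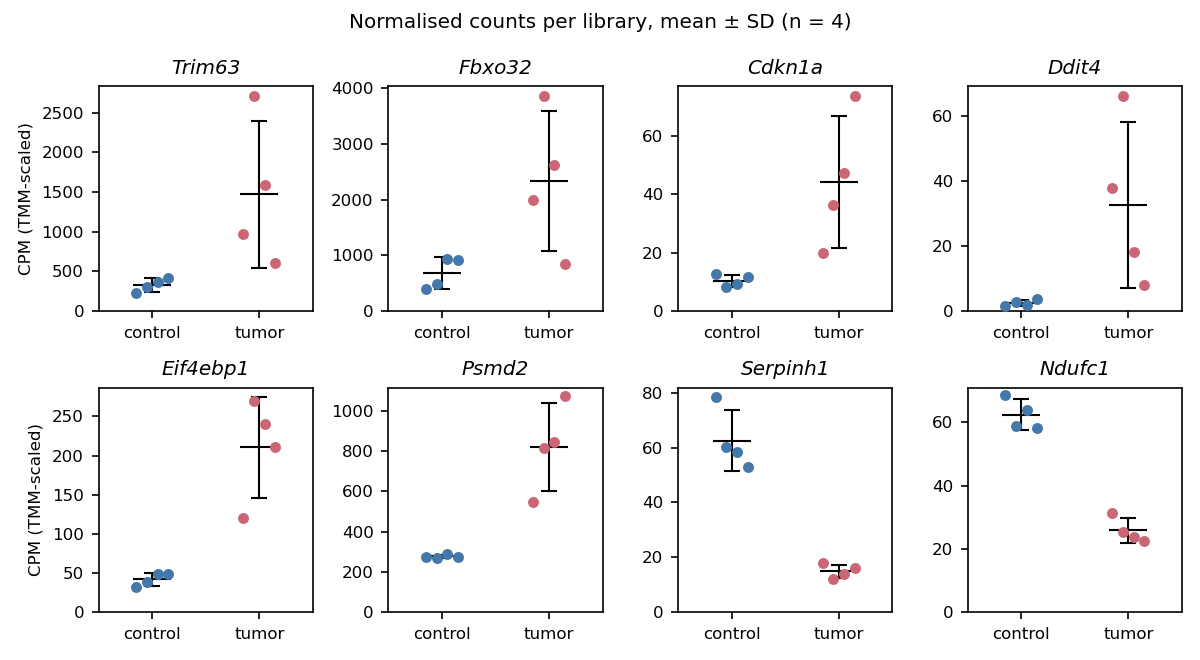
Normalised CPM of 8 genes in each of the 4 control and 4 tumor libraries (points), with the mean (bar) and SD (whiskers) of each group. Trim63 and Fbxo32 are ubiquitin ligases, Serpinh1 is a collagen chaperone and Ndufc1 a complex I subunit; the Fbxo32 groups overlap and the other 7 do not.

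The proteasome, autophagy, FOXO and atrophy lists were called by camera with a preset correlation of 0.01 between genes. The Benjamini-Hochberg adjusted p was 8.27e-20 for the proteasome, 1.25e-05 for autophagy, 4.12e-11 for FOXO or glucocorticoid targets and 0.0229 for the atrophy list. None of these calls held when camera estimated the correlation of each list: the adjusted p = 0.457 with an estimated correlation for the proteasome, autophagy and FOXO lists, and the adjusted p = 0.612 with an estimated correlation for the atrophy list. The atrophy list also lost its call without tumor library 2 (adjusted p = 0.0772), where its median went from 0.36 to 0.15. In all, camera called 24 of the 43 lists tested, 7 higher and 17 lower. It called 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and the rotation test fry called 14. Other splits of the 8 libraries gave up to 27 called lists, and up to 24 where each side held 2 mice of each group. The statements on each list therefore give counts of single genes, to be read against the 19.8% called over all genes. Some fits with 1 library left out called fewer genes in all, such as 1110 without control library 1. List counts from those fits are to be read against these lower totals. Several lists, such as the interferon (8 of 42), glycolysis, mitochondrial biogenesis and fibro-adipogenic lists, had a called share near 19.8%. That share counts both directions, and 1229 of all 14070 genes fell. All 8 interferon calls were falls, and the highest log2 fold change among the 42 tested interferon genes was -0.04. Members of a list also moved together (estimated correlation 0.79 for the proteasome and 0.843 for ribosomal proteins), so their calls are not independent.

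Most ribosomal protein and ribosome biogenesis genes rose. Of 78 cytosolic ribosomal protein genes, 49 rose (66 adjusted over the list alone), with a median log2 fold change of 0.51 and a range from 0.08 to 1.45. Rpl22 rose 1.61-fold, from 76.9 ± 3.98 to 124 ± 12.6 CPM (SD, n = 4), and Rpl30 rose 1.78-fold. Ribosomal protein genes have many processed pseudogenes, and reads shared with these leave single values uncertain. Of 28 ribosome biogenesis genes, 17 rose (22 adjusted over the list alone), with a median of 0.54. The nucleolar genes Nop14, Gnl3 and Ncl (nucleolin) rose 2.68-fold, 2.30-fold and 2.19-fold. The camera adjusted p was 9.26e-16 for the ribosomal proteins and 5.57e-12 for ribosome biogenesis (adjusted p = 0.569 and adjusted p = 0.457 with an estimated correlation). The ribosomal protein count depended on single libraries: it was 13 without control library 1, 14 without control library 2, 22 without control library 3, 25 without control library 4, 13 without tumor library 3 and 30 without tumor library 4. With the replicate number as a block the ribosomal protein count was 17, and with the fibre covariate it was 34. Fewer genes were called in all in some of these fits, with 630 higher genes without control library 1. The ribosomal protein median stayed between 0.41 and 0.59 over the alternatives. The biogenesis count was 10 without control library 1, and 11 without control library 2 or tumor library 3.

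Genes of insulin-like growth factor and mTOR signalling moved in both directions. Of 28 such genes, 10 rose and 3 fell (15 and 6 adjusted over the list alone), and 6 rose without control library 1, control library 2 or tumor library 3. The list includes Eif4ebp1 and Ddit4, which restrain translation and mTORC1, as well as the kinase gene Akt1, which rose 3.41-fold, and Igfbp3, a binding protein of the growth factor, which rose 3.10-fold. The largest fall in the list, chosen after its values were seen, was that of the growth factor gene Igf1 (3.70-fold, adjusted p = 0.00668, edgeR). Its median log2 fold change was 0.36 and its camera adjusted p was 0.00291 (adjusted p = 0.457 with an estimated correlation). Mstn (myostatin), a muscle growth inhibitor, had a log2 fold change of 0.53 ± 0.26 (adjusted p = 0.185, edgeR), which passed without control library 3 (adjusted p = 0.0341). Of 28 genes of TGF-beta, activin and myostatin signalling, 3 rose and 5 fell (the same counts adjusted over the list alone), and the list did not pass (camera adjusted p = 0.369). The higher and lower counts were 0 and 3 without control library 1, 1 and 3 without control library 2, 1 and 2 without tumor library 3, and 1 and 5 without tumor library 2. Smad3, a mediator of these signals, fell 3.41-fold, from 121 ± 25.2 to 35.5 ± 12.6 CPM. The stress cytokine gene Gdf15 had counts between 0 and 13 in each library and was not tested.

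Nuclear genes of the respiratory chain fell together. Of 36 complex I subunit genes, 26 fell (34 adjusted over the list alone), with a median log2 fold change of -0.78. Of 42 genes of complexes II to V, 32 fell (38 adjusted over the list alone), with a median of -0.79. Ndufc1 fell 2.42-fold (-1.27 ± 0.13 on the log2 scale, SE, adjusted p = 0.00217, edgeR), from 62.4 ± 4.84 to 25.8 ± 3.97 CPM (SD, n = 4), and Ndufs4 fell 1.64-fold. Cytochrome c (Cycs) fell 2.26-fold, from 352 ± 60.2 to 156 ± 16.6 CPM, and the ATP synthase subunit gene Atp5j fell 2.09-fold. The camera adjusted p was 7.93e-17 for complex I and 3.36e-18 for complexes II to V (adjusted p = 0.457 with an estimated correlation for each). Among controls the mean log2 CPM of the 78 subunits was lower the higher the Myh4 ratio, from 7.78 in control library 4 to 7.22 in control library 3. Among tumor libraries it was highest in library 2 (6.96), with the lowest ratio, and the other 3 did not follow this order. With the Myh ratio as a covariate, chosen after seeing the data, 61 of the 78 subunit genes were called and the median was -0.66, against 58 and -0.79 without it. Without tumor library 3 the counts were 16 and 16, and without control library 1 the count for complexes II to V was 19.

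**Figure D2:**
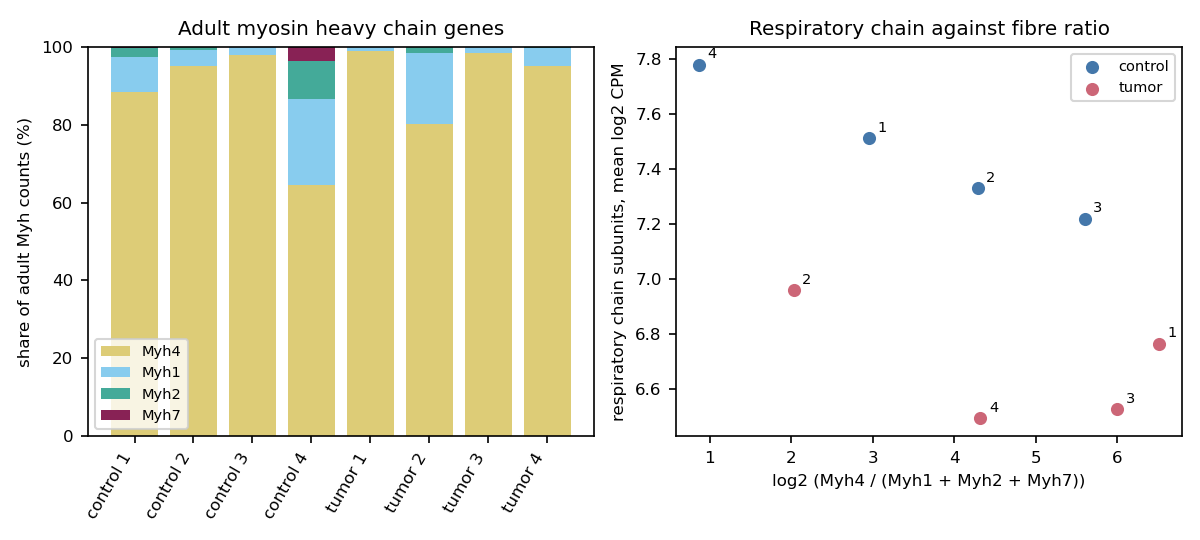
Left, share of the adult myosin heavy chain counts (percent) taken by Myh4, Myh1, Myh2 and Myh7 in each library. Right, mean log2 CPM of the 78 respiratory chain subunit genes against the log2 ratio of Myh4 to the other adult forms, 1 point per library with its replicate number; the 4 tumor libraries lie between 6.49 and 6.96 and the 4 controls between 7.22 and 7.78.

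Other mitochondrial and fuel genes fell in part. Of 27 genes of the tricarboxylic acid cycle and pyruvate entry, 12 fell (18 adjusted over the list alone), with a median log2 fold change of -0.77, including Dlat of the pyruvate dehydrogenase complex (2.35-fold) and the pyruvate carrier gene Mpc2 (1.91-fold). That count was 6 without control library 1, 4 without tumor library 3 and 19 without tumor library 2. Of 24 genes of mitochondrial biogenesis and dynamics, 1 rose and 4 fell (the same adjusted over the list alone). The regulators Esrra and Perm1 fell 2.37-fold and 4.57-fold, and the deacetylase gene Sirt3 fell 2.50-fold. Perm1 lost its call without tumor library 3 (adjusted p = 0.0582), where 2 genes of this list fell, and without tumor library 2, 8 fell, Perm1 by 7.10-fold. Ppargc1a (PGC-1alpha) had a log2 fold change of -0.55 ± 0.26 (adjusted p = 0.171, edgeR), which passed without tumor library 2 (adjusted p = 0.0419). Of the 13 protein genes of the mitochondrial genome, 2 fell over all genes and none adjusted over the list alone, with a median of -0.70. The count was 8 without tumor library 2 and 0 without any other library. mt-Co3 had the smaller p of these (-0.96 ± 0.28, adjusted p = 0.0425), and its call was lost in each left-out fit except that without tumor library 2 (adjusted p from 0.0548 to 0.122). Mitochondrial transcripts made up 12.9% to 22.7% of the counts in controls and 7.91% to 14.8% in tumor mice. Camera called these lists at an adjusted p of 1.06e-08 for the acid cycle, 0.0397 for biogenesis and 0.000597 for the mitochondrial genome (adjusted p = 0.536, adjusted p = 0.669 and adjusted p = 0.614 with an estimated correlation). The biogenesis call was lost without control library 4 (adjusted p = 0.153, median -0.16 against -0.25), tumor library 1 (adjusted p = 0.117) or tumor library 4 (adjusted p = 0.153), and with the fibre covariate (adjusted p = 0.091).

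Fat and sugar metabolism genes changed less evenly. Of 38 fatty acid oxidation genes 1 fell (the same adjusted over the list alone), with a median log2 fold change of -0.37, and the list did not pass (camera adjusted p = 0.135). Without tumor library 2, 11 fell, the median was -0.80 and the list passed (adjusted p = 8.3e-05), as it did without control library 3 (adjusted p = 0.00598). Without control library 4 the median was -0.04 (adjusted p = 0.769), and with the fibre covariate it was -0.03. For all 8 libraries the adjusted p = 0.774 with an estimated correlation. Of 24 lipid synthesis genes 6 fell (8 adjusted over the list alone), with a median of -0.71. The desaturase gene Scd2 fell 5.40-fold (-2.43 ± 0.36 on the log2 scale, adjusted p = 0.00399, edgeR) and the sterol regulator gene Srebf2 fell 1.72-fold. Srebf2 lost its call without control library 1 (adjusted p = 0.0847), control library 2 (adjusted p = 0.0615) or tumor library 3 (adjusted p = 0.0826). The lipid count was 1 without any of these 3 libraries, 2 without control library 3, 3 without tumor library 4 and 10 without tumor library 2. Adipocyte scores followed the lipid scores in part, and both lists had the same lowest log2 fold change (-3.11), that of the shared gene Scd1. Among controls, libraries 1 and 2 had the highest lipid (5.11 and 5.31) and adipocyte scores (5.88 and 6.35). Tumor library 2 had the highest tumor value of both (4.44 and 5.92), with an adipocyte score above that of control library 1. Control library 4 lay above tumor library 1 in the lipid score (4 against 3.84) but below it in the adipocyte score (2.48 against 3.21). Whether the lipid fall reflects adipocyte content was not tested. Of 30 glycolysis and glycogen genes, 1 rose and 5 fell (1 and 7 adjusted over the list alone), with a median of -0.30. Pgam2, the muscle phosphoglycerate mutase, fell 2.99-fold, from 1304 ± 175 to 435 ± 121 CPM (SD, n = 4), and Pgk1 fell 2.23-fold. Here 3 fell without control libraries 1, 2 or 3 or tumor library 3, and 10 without tumor library 1. Camera gave adjusted p values of 0.00214 for lipid synthesis and 0.00415 for glycolysis (adjusted p = 0.536 and adjusted p = 0.614 with an estimated correlation), the latter lost without tumor library 4 (adjusted p = 0.063, median -0.18).

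Part of the slow-fibre genes fell, with large differences between mice. Of 15 slow-fibre genes, 6 fell (7 adjusted over the list alone), with a median log2 fold change of -2.40. The slow myosin heavy chain Myh7 went from 575 ± 1061 to 2.16 ± 1.75 CPM (SD, n = 4), with a log2 fold change of -8.06 ± 2.13 (SE) and an adjusted p of 0.0284 in the edgeR test. Its share of the adult myosin heavy chain counts was 3.57% in control library 4, 0.0019% in control library 3 and 0.000288% to 0.00545% in tumor mice, so the groups overlapped. The slow light chain gene Myl3 fell by 8.99 ± 2.09 on the log2 scale (adjusted p = 0.0181) and the troponin gene Tnnc1 by 6.36 ± 1.85 (adjusted p = 0.0397). The slow count was 1 without control library 1, 2 without control library 4, 1 without tumor library 1, 3 without tumor library 2, 0 without tumor library 3 and 1 without tumor library 4. Myh7 lost its call without control library 1 or tumor libraries 1, 3 or 4 (adjusted p from 0.0547 to 0.0897), Tnnc1 without any single library but control libraries 2 and 3 (0.0525 to 0.114) and Myl3 without tumor library 3 (adjusted p = 0.0648). The sizes rested on control library 4: without it the folds of fall were 21.2 for Myh7, 67.0 for Myl3 and 9.79 for Tnnc1, and the list median was -0.91. Tnnc1 fell 157-fold without tumor library 2. With the fibre covariate the median was -0.89, and 1 of the 6 genes stayed called (Myl3, adjusted p = 0.0463). The list's camera adjusted p was 0.0169 (adjusted p = 0.669 with an estimated correlation), and the call was also lost without control library 4 (adjusted p = 0.145) or tumor library 1 (adjusted p = 0.0663), with a stricter count filter (adjusted p = 0.137) and with the fibre covariate (adjusted p = 0.401).

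The other adult myosin heavy chains did not differ between groups beyond the spread between mice. The log2 fold changes were -2.54 ± 1.42 for Myh2 (adjusted p = 0.235, edgeR), -0.37 ± 0.93 for Myh1 (adjusted p = 0.812) and 0.23 ± 0.37 for Myh4 (adjusted p = 0.693). The Myh1 value turned to 0.51 without control library 4 and to 0.19 with the fibre covariate, and was -2.15 without tumor library 2. Myh2 passed without tumor library 2 (-4.89, adjusted p = 0.0439) and had a value of -0.88 without control library 4. Of 17 fast-fibre genes, 2 fell (the same adjusted over the list alone). These were Casq1, the calcium-binding protein of the fast sarcoplasmic reticulum (2.83-fold), and the fast light chain Myl1 (3.05-fold, from 7829 ± 2432 to 2568 ± 1182 CPM, SD, n = 4). Myl1 lost its call without tumor library 3 (adjusted p = 0.0507), leaving 1 gene, and 6 fast-fibre genes fell without tumor library 1. The fast list had a camera adjusted p of 0.0336 (adjusted p = 0.669 with an estimated correlation). That call was lost without control library 2 (adjusted p = 0.0541), control library 3 (adjusted p = 0.0895) or tumor library 4 (adjusted p = 0.418). Its median of -0.37 was -0.57 without control library 2, -0.60 without tumor library 2 and -0.10 without tumor library 4. Of 32 structural sarcomere genes 5 rose and 2 fell, and of 25 excitation-contraction genes 1 rose and 3 fell (6 and 2, and 1 and 3, adjusted over the list alone). Neither list passed (camera adjusted p = 0.273 and 0.318). The higher sarcomere genes numbered 0 without control library 1, 3 without tumor library 2, and 1 without control libraries 2 or 3 or tumor library 3. The lower excitation-contraction genes numbered 0 without control library 1 or tumor library 3, and 1 without control libraries 2 or 3.

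Denervation and regeneration genes moved both ways. Of 28 denervation and neuromuscular junction genes, 5 rose and 7 fell, and of 22 satellite cell and regeneration genes 3 rose and 5 fell (5 and 7, and 4 and 5, adjusted over the list alone). Neither list passed (camera adjusted p = 0.408 and 0.767). The higher denervation genes numbered 2 without control libraries 1, 2 or 4 or tumor library 3, and 3 without control library 3 or tumor library 4. The lower ones numbered 4 without control library 1 and 2 without control library 2. The lower regeneration genes numbered 3 without control libraries 1, 2 or 4 or tumor libraries 1 or 3. The myogenic factor gene Myod1 fell 2.69-fold, from 26.5 ± 6.27 to 9.84 ± 3.02 CPM (SD, n = 4), while the satellite cell cadherin gene Cdh15 rose 2.72-fold, from 21.0 ± 1.26 to 57.3 ± 12.96 CPM. Chrng, the fetal acetylcholine receptor subunit that returns after denervation, had a log2 fold change of 1.09 ± 0.86 (adjusted p = 0.399, edgeR) at under 1 CPM in both groups, and of 2.78 without control library 1 (adjusted p = 0.0634).

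Part of the extracellular matrix genes fell. Of 40 matrix genes, 19 fell (21 adjusted over the list alone), with a median log2 fold change of -0.86. Serpinh1, the collagen chaperone HSP47, fell 4.15-fold (-2.05 ± 0.17 on the log2 scale, SE, adjusted p = 0.00126, edgeR), from 62.5 ± 11.1 to 15.0 ± 2.38 CPM (SD, n = 4). The basement membrane collagens Col15a1 and Col4a1 fell 5.25-fold and 2.46-fold. The camera adjusted p was 5.96e-11 (adjusted p = 0.457 with an estimated correlation). The count was 8 without control library 1, 10 without control library 2 or tumor library 3, and 12 without control library 3. Among 19 markers of fibroblasts and fibro-adipogenic progenitors, 1 rose and 3 fell (1 and 4 adjusted over the list alone), with a median of -0.57, and Pi16 fell 3.57-fold. The fallen markers numbered 1 without control library 1 or tumor library 3, 6 without control library 4 and 7 without tumor library 1. The marker list had a camera adjusted p of 0.00394 (adjusted p = 0.614 with an estimated correlation).

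Part of the vascular genes fell as well. Of 22 endothelial markers, 8 fell (9 adjusted over the list alone), with a median log2 fold change of -0.60. Kdr, the main receptor for vascular endothelial growth factor, fell 3.67-fold (-1.88 ± 0.32 on the log2 scale, SE, adjusted p = 0.00613, edgeR) and Emcn fell 2.65-fold. Of 23 hypoxia and angiogenesis genes, 2 rose and 9 fell (2 and 10 adjusted over the list alone), with a median of -0.42. Its members that fell include Kdr, Pgk1 and Apln, the peptide ligand of an endothelial receptor (7.67-fold, from 1.65 ± 0.63 to 0.21 ± 0.02 CPM, SD, n = 4). Of 15 smooth muscle and pericyte markers, 1 rose and 5 fell (2 and 5 adjusted over the list alone), with a median of -0.66, and Acta2 fell 2.38-fold. Camera gave adjusted p values of 0.00032, 0.00167 and 0.0186 for the endothelial, hypoxia and pericyte lists (adjusted p = 0.569, adjusted p = 0.487 and adjusted p = 0.669 with an estimated correlation). The pericyte call was lost without control library 4 (adjusted p = 0.0968, median -0.35) or tumor library 4 (adjusted p = 0.063) and with the fibre covariate (adjusted p = 0.0658). The endothelial count was 4 without control library 1 or tumor library 3, and 5 without control library 2. The 2 higher hypoxia genes became 1 without control library 3, and 0 without control libraries 1 or 2 or tumor libraries 2 or 3. The count of lower ones was 4 without control library 1 or tumor library 3, and 5 without control library 2 or tumor library 4. Fallen pericyte markers numbered 1 without control library 1, 2 without tumor library 3, 3 without control libraries 2, 3 or 4 or tumor library 4, and 8 without tumor library 2.

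Markers of other cells gave few calls. Of 19 adipocyte markers, 2 fell (1 adjusted over the list alone), with a median log2 fold change of -0.90 and a camera adjusted p of 0.0203 (adjusted p = 0.669 with an estimated correlation). The call was lost without control library 2 (adjusted p = 0.111) or tumor library 4 (adjusted p = 0.172). Scd1, a fat desaturase, was the larger of these falls (8.64-fold, adjusted p = 0.0464, edgeR), with overlapping groups, and it lost its call without control libraries 1, 2 or 3 or tumor libraries 1, 3 or 4 (adjusted p from 0.0641 to 0.128). Its fall was 5.44-fold without control library 2 and 13.5-fold without tumor library 2. The adipocyte count was 0 without control libraries 1 or 2 or tumor library 3, 1 without control library 3 or tumor library 4, and 10 without tumor library 2. The adipocyte median was -0.57 without control library 2, -2.87 without tumor library 2 (adjusted p = 7.49e-06) and -3.25 without control library 4 and tumor library 2, where 16 markers fell. Of 27 macrophage markers 1 rose (the same adjusted over the list alone), the scavenger receptor gene Cd163 (2.07-fold, from 4.867 ± 1.202 to 10.1 ± 1.94 CPM, SD, n = 4). The macrophage list did not pass (camera adjusted p = 0.318), but it passed without tumor library 2 (adjusted p = 0.00059), where 5 markers rose. Schwann cell, red cell and tendon markers did not pass as lists (camera adjusted p = 0.318, 0.327 and 0.135), with 0 of 11, 2 of 11 and 1 of 14 genes called. They passed without tumor library 2 (Schwann, adjusted p = 0.0401), tumor library 1 (red cell, adjusted p = 0.0209) and tumor library 3 (tendon, adjusted p = 0.0165). The tendon list also passed with the fibre covariate (camera adjusted p = 0.0406) and with the replicate number as a block (camera adjusted p = 0.0365). Of the neutrophil, T and natural killer cell, and B cell markers, 4, 2 and 3 were counted deeply enough, too few for a list test, and 1, 0 and 1 of them were called. S100a8 of neutrophils rose from 0.13 ± 0.19 to 1.30 ± 0.79 CPM (adjusted p = 0.044), and its call was lost in each left-out fit except that without control library 3 (33.5-fold there; adjusted p from 0.0504 to 0.105 in the others).

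Squamous epithelial markers were followed as a sign of carcinoma cells in the muscle. Keratin genes Krt5, Krt14, Krt6a and Krt17 had 0 counts in all 8 libraries, which allows up to 0.109 CPM (3 counts at the lowest scaled depth, counting error only). Whether the injected cells express these 4 genes was not measured here. Krt80, a keratin gene outside this list, rose 11.3-fold, with the lost calls given above. It lay between 0.50 and 1.63 CPM in controls and reached 43.64 CPM in tumor library 4. Of the 6 markers that could be tested, 2 rose and 1 fell (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.135), but it passed without tumor library 3 (adjusted p = 0.0491) and by fry (adjusted p = 0.0152), among other settings. Trp63 rose 3.01-fold, from 8.17 ± 1.43 to 24.6 ± 8.86 CPM (SD, n = 4, adjusted p = 0.00484, edgeR), and the junction gene Jup rose 1.47-fold. Jup lost its call without control libraries 1, 2 or 3 or tumor libraries 2, 3 or 4 (adjusted p from 0.0549 to 0.107), where 1 marker rose. Krt10 fell 2.12-fold at about 1 CPM, a call lost in each left-out fit except that without tumor library 1 (adjusted p from 0.0519 to 0.109).

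Interferon-stimulated genes fell in part, and genes of other inflammatory lists moved both ways. Of 42 interferon-stimulated genes, 8 fell (the same adjusted over the list alone), with a median log2 fold change of -0.58 and a range from -2.22 to -0.04. Gbp6 fell 4.66-fold and the immunoproteasome gene Psmb10 2.03-fold. The proteasome genes named above, which rose, belong to the regulatory particle, so a change of catalytic subunits is not shown. Psmb10 lost its call without tumor library 3 (adjusted p = 0.0512). The interferon list had a camera adjusted p of 2.27e-06 (adjusted p = 0.457 with an estimated correlation). Its count was 3 without control libraries 1 or 2 or tumor library 3, 4 without control library 3, 5 without tumor library 4 and 14 without tumor library 1, where the median was -0.91. Of 24 IL-6, STAT3 and acute phase genes 5 rose and 1 fell, and of 18 NF-kB target genes 4 rose and 3 fell (5 and 1, and 5 and 3, adjusted over the list alone). Neither list passed (camera adjusted p = 0.109 and 0.414), but the former passed by fry (adjusted p = 0.0152) and with a stricter count filter (camera adjusted p = 0.0382). The higher genes numbered 3 in the former without control libraries 2 or 3 or tumor library 3. In the latter they numbered 1 without control libraries 1 or 2 or tumor library 3, and 2 without control library 3, and the lower genes numbered 1 without control library 1 or tumor library 3. Cebpd belongs to the former, and the NF-kB inhibitor gene Nfkbia rose 1.80-fold while Tnfaip2 fell 3.14-fold.

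Among stress genes, cytosolic chaperones moved in both directions. Of 23 chaperone genes, 2 rose and 6 fell (2 and 7 adjusted over the list alone), with a median log2 fold change of -0.33. Hspa8 fell 2.40-fold, from 1107 ± 53.1 to 461 ± 173 CPM (SD, n = 4), and its partner Dnaja1 fell 2.17-fold, whereas Hsp90ab1 rose 1.88-fold. The camera adjusted p was 0.0358 (adjusted p = 0.669 with an estimated correlation), and the call was lost without control library 4 (adjusted p = 0.0968), tumor library 1 (adjusted p = 0.295) or tumor library 3 (adjusted p = 0.0511) and with the fibre covariate (adjusted p = 0.206). The fallen chaperones numbered 2 without control libraries 1 or 2 or tumor library 3, and 3 without tumor library 1. Of 30 endoplasmic reticulum stress genes 5 rose and 1 fell, and of 27 antioxidant genes 6 rose and 2 fell (5 and 1, and 10 and 6, adjusted over the list alone). Neither list passed (camera adjusted p = 0.17 and 0.135), though both did without tumor library 1 (adjusted p = 0.0472 and 0.049). The higher reticulum stress genes numbered 1 without control libraries 1 or 2, 2 without control libraries 3 or 4 or tumor libraries 2 or 3, and 3 without tumor library 4. The higher antioxidant genes numbered 2 without control library 1, and 3 without control library 2 or tumor library 3. Ppp1r15a, which reverses the translational block of the stress response, rose 2.91-fold (1.54 ± 0.19 on the log2 scale, adjusted p = 0.00294, edgeR).

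Of 19 circadian clock genes, 6 rose and 3 fell (the same adjusted over the list alone), and the list lay at the threshold (camera adjusted p = 0.0503, and adjusted p = 0.457 with an estimated correlation). It passed without control library 3 (adjusted p = 0.0305), control library 4 (0.00464), tumor library 3 (0.0426) or tumor library 4 (0.0333), and by fry (0.0167). Cry2 rose 2.67-fold, from 27.4 ± 5.14 to 73.1 ± 9.03 CPM (SD, n = 4), and Per1 is given above. Of 24 genes of polyamine and branched-chain amino acid metabolism, 2 rose and 4 fell (3 and 5 adjusted over the list alone), without passing as a list (camera adjusted p = 0.208). Without tumor library 2, 7 fell and the list passed (adjusted p = 0.0348), and 2 fell without tumor library 3. Amd1, a key enzyme of polyamine synthesis, fell 7.12-fold, from 1234 ± 499 to 173 ± 109 CPM, with the uncertainty that its reads are shared with near-identical copies. Of 20 proliferation genes 1 rose and 3 fell, and of 19 immediate early genes 2 rose and 4 fell (1 and 3, and 3 and 4, adjusted over the list alone). Neither list passed (camera adjusted p = 0.57 and 0.481), and the proliferation list had a median of 0.01 and a mean of -0.01. Over the fits with 1 library left out, that median ran from -0.20 without tumor library 4 to 0.36 without control library 3. The lower proliferation genes numbered 0 without control library 1, and 1 without control library 2 or tumor library 3. The lower immediate early genes numbered 1 without control library 1 or tumor library 3, and 2 without control libraries 2 or 4 or tumor libraries 1 or 4.

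**Figure D3:**
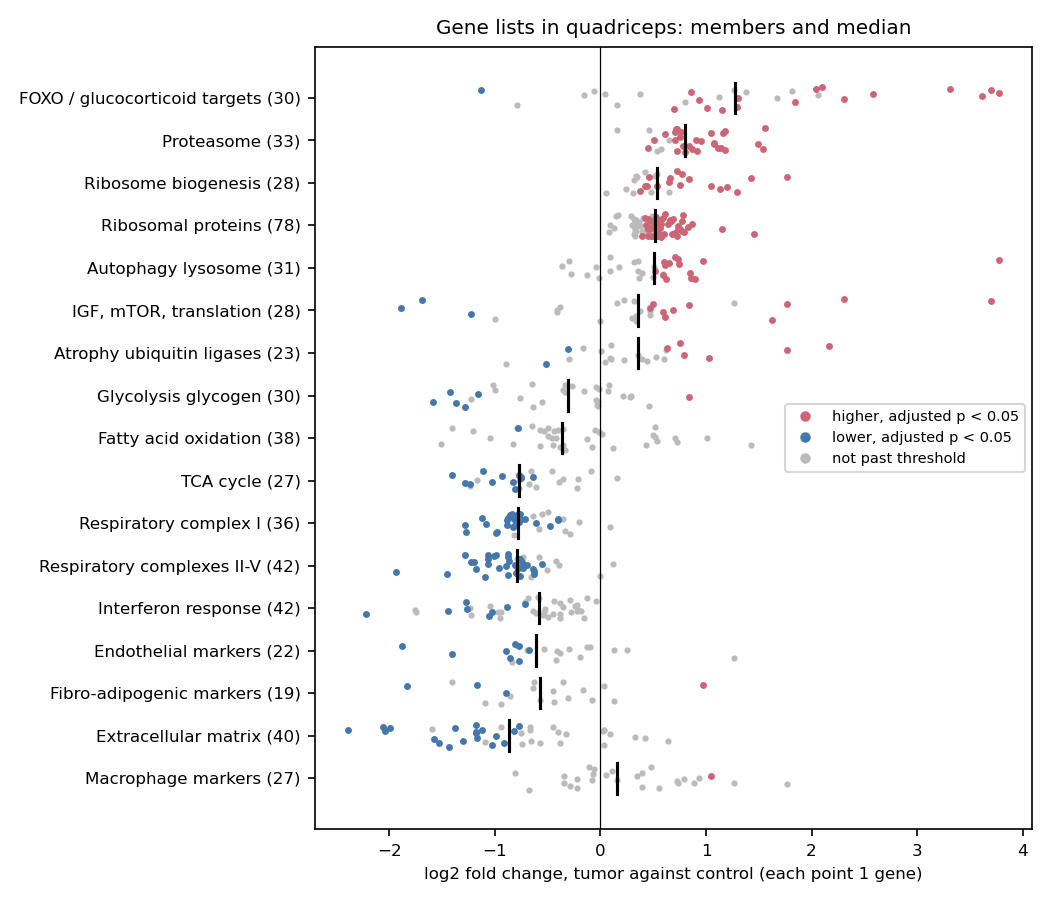
Log2 fold change (tumor against control) of each tested member of 17 gene lists, 1 point per gene, with the list median as a vertical bar and the number of tested members in brackets. Red points are genes higher and blue points genes lower at an adjusted p under 0.05 over all genes; the median was 0.80 for the proteasome, -0.78 for complex I and -0.86 for the extracellular matrix.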

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

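The tests chosen after the result was seen were those of a smaller share of all non-fibre cells, of fewer fibroblasts, of a lower muscle temperature and with the fibre ratio as a covariate, and 1 criterion of the matched-gene test. Within each group of 4 libraries, a library was taken as standing off when its Dixon ratio passed the critical value for 4 values, which chance gives in about 1 group in 20. This was met in 19 of 292 groups (6.51%). In tumor library 1 it was met by high values of Amd1 (ratio 0.858), Nrep (0.845) and Pgam2 (0.899). Tumor library 2 had high values of Hspa8 (0.87), Kdr (0.832) and Ppargc1a (0.878) and a low value of Smad3 (0.86). Tumor library 4 had low values of Cebpd (0.892), Per1 (0.835) and the circadian list score (0.949). Control library 4 had high values of Ppargc1a (0.869) and Usp2 (0.856) and a low interferon score (0.835). Control library 3 had high values of Psmd4 (0.832), the proteasome score (0.87) and the TGF-beta score (0.875) and a low value of Foxo6os (0.847). Emcn was high in control library 1 (0.839) and Foxo1 low in control library 2 (0.93).

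For the lower respiratory chain and slow-fibre genes, the tests with the fibre ratio as a covariate, for a smaller share of slow and oxidative fibres, were chosen after the fibre differences were seen. With the Myh ratio as a covariate, the median log2 fold change of the 78 respiratory subunits was -0.66 against -0.79 without it. Most of this fall was therefore not accounted for by the ratio. The ratio did not remove the slow-fibre difference either: the median of the 6 slow-fibre genes called in the full fit went from -6.32 to -2.55. A difference in fibre composition that the ratio misses therefore stays open. Of the 6 slow-fibre genes, 1 stayed called. Myh7 is 1 of the 6 and also part of the ratio, so the loss of calls is partly built in. A difference in where the muscle was sampled and a loss of slow fibres would both move the ratio, so they cannot be told apart. A bias with transcript length, GC content or abundance was tested with 20 matched genes per subunit, whose median log2 fold change was 0.21, of the opposite sign to that of the subunits. Its size missed the bound set in advance (under 25% of the subunits' change), and the criterion of an opposite sign, by which the value argues against this bias, was added after the value was seen.

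For the higher proteasome and ribosomal protein genes, no tests were chosen after the result was seen. Matched genes had a median log2 fold change of 0.16 for the proteasome and 0.05 for the ribosomal proteins, against list medians of 0.80 and 0.51. These values argue against a bias with transcript length, GC content or abundance. Scaling without the mitochondrial and the 50 most abundant genes gave medians of 0.79 and 0.50. The TMM method already trims the most abundant genes when it computes the factors of the main fit. Leaving such genes out could therefore hardly move the medians. Scaling set by a few abundant transcripts is not decided by this test and stays open.

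For the lower matrix, fibroblast and endothelial genes, the tests of 2 explanations were chosen after the result was seen, namely a smaller share of all non-fibre cells and fewer fibroblasts. Matched genes had a median log2 fold change of 0.06, which argues against a length or GC bias. The matrix score minus the macrophage score was lower in tumor mice by 1.08 on the log2 scale (difference -1.08, exact permutation p = 0.0286, 0.0857 after Benjamini-Hochberg), so the macrophage markers did not fall with the matrix genes. Macrophages were the only reference, and their median was -0.23 with the fibre covariate. The endothelial, pericyte, adipocyte, Schwann and tendon medians were negative in the full fit, while that of 4 neutrophil markers was positive. A smaller share of non-fibre cells other than macrophages therefore stays open. The matrix score minus the fibroblast marker score differed by -0.44 (exact permutation p = 0.0571, 0.0857 after Benjamini-Hochberg), so fewer fibroblasts and less matrix expression per fibroblast cannot be told apart.

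Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many called genes as found (2781, against at most 43 in the others). For gene lists, 5 of the 35 splits, the real one included, gave at least 24 calls. Of the other 4, 3 (with up to 27 calls) set 3 mice of a group and 1 of the other on each side and so keep part of the group difference, and 1 (24 calls) was balanced, among 18 balanced splits.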

How the results depend on the processing

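With other settings the 2781 calls (1552 higher, 1229 lower) ran from 1932 with the replicate number as a block, or 2343 without a count filter, to 4982 (2616 and 2366) by limma-voom with quality weights. DESeq2 gave 3487, limma-voom 2770, upper-quartile scaling 2716, scaling without abundant genes 2726 and a stricter filter 2898. With 1 library left out the count ran from 1110 to 2845, with 630 to 1551 higher and 480 to 1450 lower, and no call shared with the full fit changed sign. The lowest counts came without control library 1 (1110), tumor library 3 (1190) and control library 2 (1373), and the cause was not tested. A fold of at least 2 left 903 (352 and 551), an adjusted p under 0.01 left 759 (461 and 298), and a test against a fold of 1.2 (glmTreat) left 1363 (747 and 616). With the fibre covariate, added after the data were seen, 3032 genes were called, 2471 of them shared, and without control library 4 and tumor library 2, also added later, 2922 were called, 2208 of them shared. Of the 99 named genes tested, 89 were called and 68 of these were called in all 8 left-out fits. The limma-voom test lost Myh7 (adjusted p = 0.307), Myl3 (0.49), Tnnc1 (0.504), Krt80 (0.183), Scd1 (0.148), Foxo1 (0.0955), Nfkb2 (0.0913), Map3k14 (0.0775) and Ggt6 (0.0807), and DESeq2 gave Myh7 no adjusted p. The log2 fold change of Myh1 ran from -2.15 without tumor library 2 to 0.51 without control library 4 (adjusted p = 0.747), and was 0.19 with the fibre covariate (adjusted p = 0.632).

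Lists called numbered 24 (7 higher, 17 lower), 20 to 27 with 1 library left out (7 to 9 higher, 12 to 20 lower), and 22 by camera on limma-voom values. They numbered 14 by fry (9 higher, 5 lower) and 0 by camera with an estimated correlation (0 higher, 0 lower; 4 at an unadjusted p under 0.05).

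With the replicate number as a replicate block 1932 genes were called (1014 higher, 918 lower) and 28 lists. Whether the numbers pair the mice is not stated in the sources used here. Deviations of same-numbered libraries correlated at 0.03, 0.13, 0.20 and 0.02, and those of differently numbered ones at -0.31 to 0.15. Of the 8 libraries, 4 correlated best with the one of their own number. These weak correlations do not decide whether the mice were paired.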

Other observations

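Eda2r, Nfkb2 and Map3k14 were chosen after their values were seen, Relb by the naming rule, and the 4 were not tested as a group. Eda2r, a receptor of the tumor necrosis factor family, rose 4.12-fold (2.04 ± 0.35 on the log2 scale, SE, adjusted p = 0.00593, edgeR), from 28.6 ± 10.8 to 118 ± 49.5 CPM (SD, n = 4). It was called in all 8 fits with 1 library left out (highest adjusted p 0.0248). Nfkb2 rose 4.39-fold (adjusted p = 0.0366), Relb 2.54-fold (adjusted p = 0.0237) and Map3k14, which encodes the kinase NIK, 1.98-fold (adjusted p = 0.0494). Nfkb2 lost its call without control libraries 1, 2, 3 or 4 or tumor library 3 (adjusted p from 0.0602 to 0.0999), with a 2.09-fold rise without tumor library 4, and Relb without control libraries 1, 2 or 4 or tumor library 3 (adjusted p from 0.05 to 0.0759). Map3k14 lost it in each left-out fit except that without tumor library 1 (adjusted p from 0.069 to 0.137).

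The growth factor gene Igf1, also chosen after its values were seen, fell 3.70-fold (-1.89 ± 0.33 on the log2 scale, adjusted p = 0.00668, edgeR) and was called in all 8 left-out fits. Its binding protein gene Igfbp5 had a log2 fold change of -1.69 ± 0.47 (adjusted p = 0.0328), a call lost without control libraries 1, 2 or 3 or tumor library 3 (adjusted p from 0.0737 to 0.1).

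The cold-induced RNA-binding protein genes Cirbp and Rbm3, chosen after their values were seen, rose 2.76-fold (1.47 ± 0.13 on the log2 scale, adjusted p = 0.0018, edgeR) and 2.77-fold (adjusted p = 0.00355). Cirbp went from 21.0 ± 1.75 to 58.1 ± 8.42 CPM (SD, n = 4). As a hypothesis, muscle temperature could have been lower in tumor mice. The median log2 fold change of 7 heat shock chaperone genes was -1.12. This test was chosen after the falls of Hspa8 and Dnaja1, both among the 7, were seen. It therefore does not bear on the hypothesis, which stays open. Recording muscle temperature on day 36 in such mice, and housing them at thermoneutrality, would test it.

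Clock genes were moved in tumor mice, with Npas2 down 4.42-fold (adjusted p = 0.0108, edgeR), while Arntl (-0.50 ± 0.43, adjusted p = 0.434) and Nr1d1 (-0.41 ± 0.17, adjusted p = 0.117) did not pass. Nr1d1 passed with the fibre covariate (adjusted p = 0.0254). The mean log2 CPM of the output genes Dbp, Nr1d1, Nr1d2, Tef, Hlf and Per3 minus that of Arntl, Npas2 and Clock went from 2.27 ± 0.51 to 3.22 ± 0.72 (difference 0.95, exact permutation p = 0.0857). A shift of clock phase or of the hour of collection and a direct effect on single genes cannot be told apart, and muscle collected at several hours of the day would separate them.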
